A study of Mus musculus with 59 samples.

How the data were processed

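RNA from the prefrontal cortex of C57BL/6J mice at postnatal day 25 was measured by RNA sequencing of poly(A)-selected RNA with a stranded kit, per the labels' protocols. The labels give genotype, treatment, sex and a replicate number for each of 59 libraries, and samples were grouped by these labels alone. They do not state that each library came from a different animal, so p-values measure the spread between these samples. The deposited values were taken as a normalized signal: counts divided by a factor per library, as the authors deposited them in 1 table of 51456 genes. Per the submitters' processing notes, Salmon 0.11.2, R 3.6.0, DESeq2 1.19.11 and the genome build GRCm38 were used; the notes used here give no role or order for them. The values sum to 30.3 to 33.7 M per library and are not whole numbers, since estimated counts need not be whole, so no count model was fitted. The most frequent low value per library (0.854 to 1.31, held by 26 to 132 genes) was taken as the value of 1 read. This puts the depth at an estimated 25.8 to 36.9 M reads. No library duplicated another (correlations of log2 values from 0.966 to 0.991). Salmon divides reads among similar transcripts, so genes with near-identical copies, such as those of ribosomal proteins, have uncertain values. Gene symbols were matched for 51285 of the identifiers and not for 171, and 17301 genes were at 0 in every library. The position of Chd8 comes from the GRCm38 annotation.

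All comparisons used limma 3.58.1 (R 4.3.3, statmod 1.5.0) on log2(value + 1), with 16839 genes whose mean over all libraries was at least 10. Fold changes are on that scale, which understates changes of low genes. A single model held a mean for each of the 12 groups, with trend and robust empirical Bayes shrinkage and Benjamini-Hochberg adjustment, and calls were made at 0.05. Errors after ± are SE for log2 fold changes and SD for normalized counts. Contrasts were genotype within vehicle and within each drug, each drug against vehicle within genotype, 7 interactions and sex in WT-labelled vehicle libraries. The design for counts that had been written first was not used, because the table held normalized values; the design written for that case was. Chd8 was also tested by an exact two-sided permutation test in each stratum. The groups, contrasts, tests, the 41 gene lists (17 of cell type markers and 24 of processes), the rule for named genes and most alternatives were fixed before the data were examined. The contrasts averaged over strata, the tests of list means and the covariates for the first principal component and for striatal markers were chosen after. So were the fits without 8 libraries over 5 robust SDs above the median of an off-target marker list. All 8 were flagged by the striatal list. Olfactory bulb markers reached only 1.19 robust SDs above their median, so libraries rich in them were kept.

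Lists were tested with camera, two-sided, with a preset correlation of 0.01, adjusted over the 41 lists of each contrast, and again with a correlation estimated from the data and with fry. Camera compares a list with other genes, whereas fry tests whether its genes move on balance one way. Over the 14 genotype and drug comparisons of single strata, 106 of 574 list tests passed with the preset correlation, 0 with the estimated one and 1 with fry. Among the averaged contrasts, the endoplasmic reticulum and amino acid stress list after lithium alone held with the estimated correlation. Fry passed 5 lists for averaged lithium, 2 for averaged genotype and 0 for averaged fluoxetine and sex. Those for lithium included the stress, interferon, oxidative phosphorylation and meningeal lists, and those for genotype the glutamatergic postsynaptic list. Named genes were, in each main comparison, Chd8, all called genes where fewer than 10 were called, the 8 largest in each direction with a mean of at least 50 otherwise, 3 with the smallest p where none was called, and the 4 members with the smallest p of any list that passed. In genotype contrasts under a drug and in interactions, up to 4 called genes per direction were named. For averaged contrasts the 12 genes per direction with the smallest p, and single members of lists, were chosen after their values were seen, as were Tmem106c and Crlf2 in the genotype contrasts under a drug. Correlations of fold changes across genes were set against 100 simulations without effects that kept the shared libraries.

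Alternatives were limma without trend and robust shrinkage, TMM factors computed on the values (trimming 30% of log ratios and 5% of levels), no filter beyond a value above 0, a pseudocount of 0.5, the groups of a contrast alone, the replicate number as a block, and each library left out in turn. TMM factors moved the median of all genes by at most 0.00797. The model was tested on simulated data with known changes among 16839 genes. For lithium in HT-labelled males it recovered 32.8, 58.2 and 78.8% of genes changed by 0.25, 0.5 and 1 on the log2 scale, with 7 false calls. For lithium averaged over strata it recovered 71.6, 86.6 and 95.5%, with 5 false calls. Data simulated without change gave 2 calls over 26 comparisons. Each simulated gene varied independently of the others, so these rates leave out variation that genes share in the real libraries. Other splits of the real libraries called up to 4448 genes for lithium in HT-labelled males. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Some genes that the naming rule takes are not reported here.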

Results

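Polyadenylated RNA from the prefrontal cortex of C57BL/6J mice was profiled at postnatal day 25 in 59 libraries. The pups had received fluoxetine, lithium or vehicle through maternal milk from day 3 to day 24. The labels name no dam or litter, so p-values of all drug comparisons treat libraries as independent and do not measure the spread between treated dams. Fluoxetine blocks the reuptake of serotonin, and lithium inhibits inositol monophosphatase and glycogen synthase kinase 3. The labels name the allele Chd8-S62X and divide the libraries by genotype at Chd8, by treatment and by sex. Chd8 encodes a chromatin remodeller linked to autism. Each of the 12 groups held 5 libraries except the heterozygous (HT) females given fluoxetine, which held 4. Normalized counts summed to between 30.3 and 33.7 M per library. The most frequent low value put the original depth at an estimated 25.8 to 36.9 M reads. The most abundant gene took 2.11 to 3.19% of a library. Of 51456 listed genes, 16839 had a mean of at least 10 normalized counts and were tested. The median standard error of a log2 fold change was 0.102 in a comparison of 5 libraries with 5. Xist, the X-inactivation transcript, lay between 22800 and 41970 normalized counts in the 29 female libraries and between 0 and 136 in the 30 male libraries.

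Markers of tissue outside the cortex varied between libraries. The mean log2 level of 5 olfactory bulb markers, among them Cdhr1, Tbx21 and Eomes, ran from 4.60 to 11.1 with a median of 8.24. This level followed the first principal component of all tested genes, which carried 19.4% of the variance (59 libraries, Pearson r = 0.932, Spearman rho = 0.969, both permutation p = 1e-05, two-sided, the smallest that 100000 permutations can give, and r = 0.931 without the 2 libraries farthest from the median). Markers of excitatory neurons had a median correlation of −0.839 with this component and markers of inhibitory neurons one of 0.793. Striatal markers such as Drd1, Drd2 and Adora2a had a median level of 8.24 and reached 11.03 in replicate 2 of the WT-labelled lithium males. A total of 8 libraries lay over 5 robust SDs above the median of the striatal list: HT-labelled fluoxetine female replicates 1 and 2, lithium female replicate 5, lithium male replicates 1 and 4 and vehicle female replicate 3, and WT-labelled lithium male replicate 2 and vehicle female replicate 5.

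**Figure D1:**
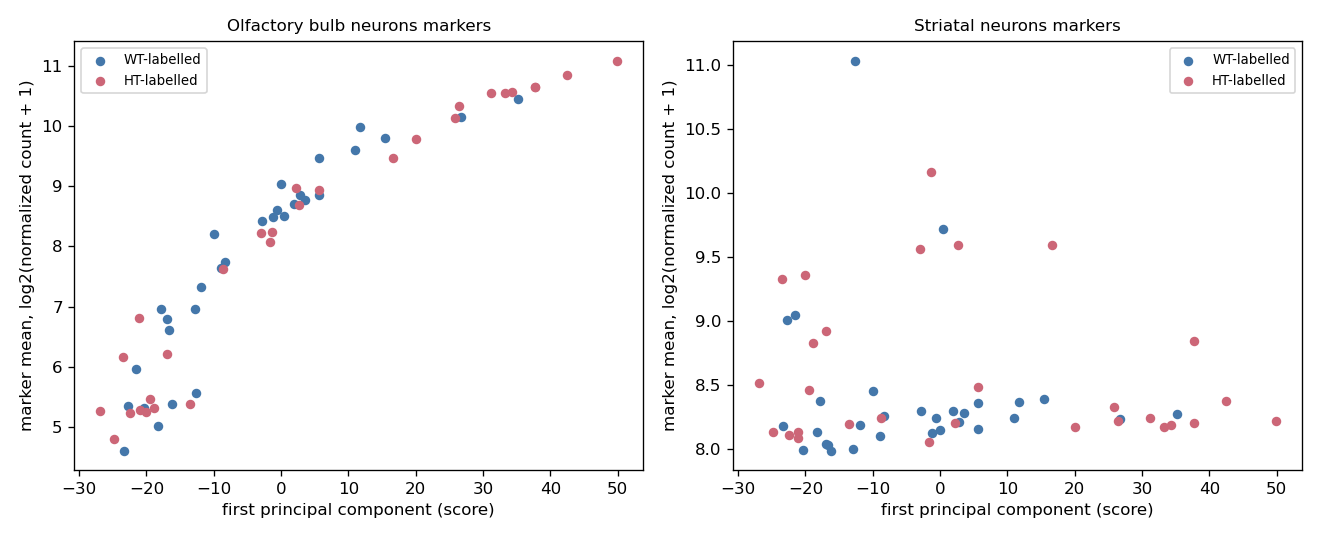
Mean log2(normalized count + 1) of the olfactory bulb markers (left) and of the striatal markers (right) against the score on the first principal component, with 1 point per library coloured by labelled genotype. The olfactory bulb level follows the component (r = 0.932), whereas the highest striatal levels, up to 11.03, occur in single libraries.

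Chd8 (ENSMUSG00000053754, minus strand of chromosome 14, 52198151 to 52257780 in GRCm38) was higher in the libraries labelled HT in every treatment and sex. In vehicle males it stood at 5621 ± 376 normalized counts in the HT-labelled libraries and 3589 ± 171 in the WT-labelled libraries (SD, n = 5 and 5). In vehicle females it stood at 5804 ± 408 and 3582 ± 235 (SD, n = 5 and 5). With fluoxetine the HT-labelled and WT-labelled means were 6224 ± 292 and 3604 ± 294 in males (SD, n = 5 and 5) and 5643 ± 108 and 3519 ± 519 in females (SD, n = 4 and 5). With lithium they were 6112 ± 321 and 3897 ± 332 in males and 6068 ± 364 and 3746 ± 142 in females (SD, n = 5 each). The fold ranged from 1.56 to 1.73, and the lowest of the 29 HT-labelled libraries (5115) lay above the highest WT-labelled library (4229). The exact two-sided permutation p was 0.00794 in each of the 6 comparisons, the smallest that 5 against 5 or 4 against 5 libraries allow, and the limma adjusted p ranged from 2.48e-12 to 3.66e-09. A heterozygous mutation that lowers the RNA of its gene would give the opposite direction. Genotypes are therefore given throughout as HT-labelled and WT-labelled, and every genotype direction rests on those labels.

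**Figure D2:**
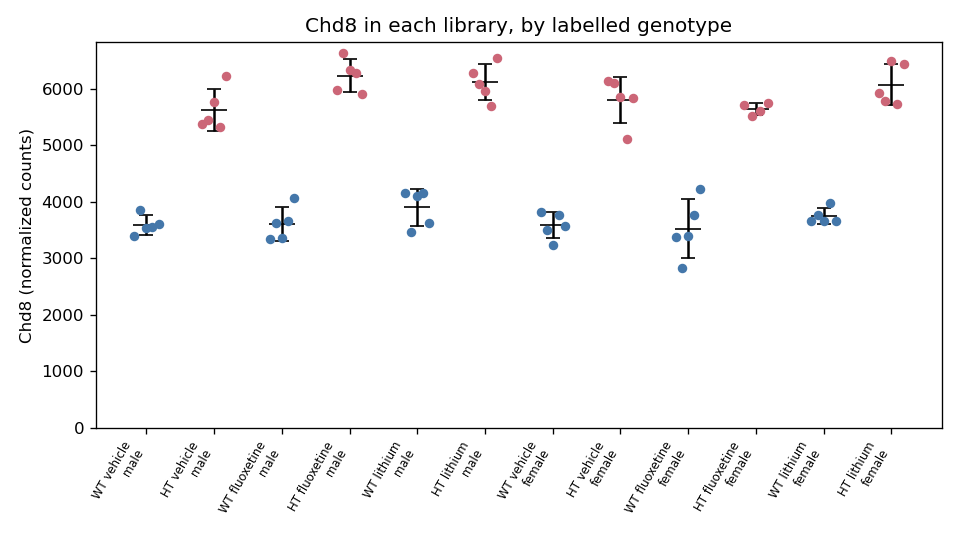
Normalized counts of Chd8 in each of the 59 libraries (points), by labelled genotype, treatment and sex, with the mean and SD of each group (bars). The HT-labelled libraries lie between 5115 and 6626 and the WT-labelled libraries between 2828 and 4229.

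In vehicle males, the comparison of HT-labelled with WT-labelled libraries addresses the effect of the Chd8 allele without a drug. Apart from Chd8, Minar2 fell by 0.37 ± 0.054 on the log2 scale, from 1240 ± 82.9 to 956 ± 42.1 normalized counts (SD, n = 5 and 5). Usp11, a deubiquitinase gene, fell by 0.30 ± 0.050, and Chmp2a, which encodes a subunit of the ESCRT-III membrane-sealing complex, rose by 0.18 ± 0.035 (log2 fold change ± SE). These 4 genes were all that limma called among 16839 at an adjusted p under 0.05 (2 higher, 2 lower, adjusted p from 3.66e-09 to 0.0138), with 1378 at an unadjusted p under 0.05. Postsynaptic glutamatergic genes had a median log2 difference of −0.085, and 20 of 25 lay below 0 (camera with a preset correlation, adjusted p = 0.0105, and adjusted p = 0.859 with an estimated correlation). Among them Gria3, an AMPA receptor subunit gene, had −0.21 ± 0.081. GABA receptor genes had a median of −0.109 with 13 of 15 below 0 (adjusted p = 0.0233, and 0.859 as the p with an estimated correlation). Immediate early genes had a median of 0.302 with 16 of 18 above 0 (adjusted p = 0.0233, and 0.859 as the p with an estimated correlation), chromatin regulators one of 0.055 and proteasome subunits one of −0.038 (both adjusted p = 0.0233, and both 0.859 as the p with an estimated correlation). No member of these 5 lists was called over all genes or adjusted over the list alone. The call of Chmp2a ended without HT-labelled vehicle male replicate 1 or 5 or WT-labelled vehicle male replicate 1, 2 or 3 (adjusted p from 0.0527 to 0.119), and with no filter on low values (0.0504). When only the 2 groups were fitted, 1 gene, Chd8, was called.

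In vehicle females, Chmp2a rose by 0.30 ± 0.035 in the HT-labelled libraries, from 1645 ± 87.7 to 2020 ± 92.1 normalized counts (SD, n = 5 and 5), and Usp11 fell by 0.27 ± 0.050. Parva, which encodes an actin-binding protein of focal adhesions, rose by 0.32 ± 0.063 and Ehd1, which acts in endosomal recycling, by 0.45 ± 0.088. With Chd8 these were the 5 genes called by limma (4 higher, 1 lower, adjusted p from 2.79e-10 to 0.0195), with 968 at an unadjusted p under 0.05. Immediate early genes had a median of −0.236 with 18 of 18 below 0 (camera adjusted p = 0.0143, and 0.948 as the p with an estimated correlation), the opposite sign to vehicle males. The glutamatergic postsynaptic list again lay below 0 in 20 of 25 members, with a median of −0.052 (adjusted p = 0.0143, and 0.948 as the p with an estimated correlation). Myelin genes had a median of −0.18 (15 of 15 below 0), cytosolic ribosomal proteins 0.039 (59 of 78 above), voltage-gated channels −0.053 (18 of 23 below), cholesterol synthesis genes −0.047 (20 of 24 below), interferon response genes 0.092 (14 of 19 above) and autism risk genes −0.047 (25 of 32 below). Their camera adjusted p lay between 0.000108 and 0.0449, and each had 0.948 as the p with an estimated correlation. No member of these 8 lists was called over all genes or adjusted over the list alone. The count was 2 without HT-labelled vehicle female replicate 1 and 3 without WT-labelled replicate 2, 4 or 5, as the calls of Usp11 (without HT-labelled replicate 1, adjusted p = 0.0642), Parva (without HT-labelled replicate 1, 4 or 5 or WT-labelled replicate 2, 3, 4 or 5, 0.0606 to 0.096) and Ehd1 (without HT-labelled replicate 1 or 5 or WT-labelled replicate 1, 2, 4 or 5, 0.0574 to 0.109) ended. It was 2 with the 2 groups alone, 15 with the first principal component as covariate and 8 without the 8 libraries of high striatal markers.

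Fluoxetine was compared with vehicle in each genotype and sex, to see which genes the drug moved and whether it moved them against the genotype. In WT-labelled males, the ribosomal protein genes Rpl14 and Rpl21 rose by 0.33 ± 0.055 and 0.20 ± 0.043. Rpl14 went from 2184 ± 145 to 2737 ± 166 normalized counts (SD, n = 5 and 5). Cdc73, a component of the PAF1 transcription complex, fell by 0.40 ± 0.076, the ciliary gene Rpgrip1l by 0.32 ± 0.066 and the gene model Gm49599 by 0.99 ± 0.195. These were the 5 genes called by limma (adjusted p from 0.00504 to 0.0491), with 1584 at an unadjusted p under 0.05. Ribosomal protein genes have many near-identical processed copies, so their single values are uncertain. The list of cytosolic ribosomal proteins had a median of 0.097, with 2 of 78 members called over all genes and 29 higher and 1 lower adjusted over the list alone (camera adjusted p = 4.36e-17, and 0.765 as the p with an estimated correlation). Mitochondrial ribosomal proteins had a median of 0.071 (0 called over all genes, 2 adjusted over the list alone) and oxidative phosphorylation one of 0.060 (0 and 0), with an adjusted p of 0.402 and 0.992 with an estimated correlation. Meningeal fibroblast markers had a median of −0.37 and a list mean of −0.357 ± 0.21 in the same comparison (camera adjusted p = 0.00296, and 0.992 as the p with an estimated correlation). The list rested on single libraries, with a mean of −0.165 (camera adjusted p = 0.348) without vehicle male replicate 5, where Col1a1 reached 7053 normalized counts, and of −0.162 (0.411) without fluoxetine male replicate 1. The count of genes was 1 without WT-labelled fluoxetine male replicate 1 or 2, 2 without vehicle male replicate 1, 2 or 4, 3 without vehicle male replicate 3 or 5, 21 without fluoxetine male replicate 3 and 106 without fluoxetine male replicate 5. It was 0 with the 2 groups alone, 3 with TMM factors or without trend, and 38 with the first principal component as covariate. Rpl21 and Rpgrip1l no longer passed with TMM factors (adjusted p = 0.062 and 0.0559), without trend (0.0649 each) or with no filter (0.0791 each), nor did Rpl21 with the striatal marker level as covariate (0.0605) or without the libraries of high striatal markers (0.107). Of these WT-labelled male libraries, leaving out fluoxetine replicate 1 or 2 ended the calls of Cdc73, Gm49599, Rpgrip1l and Rpl21. So did vehicle replicate 2 or 5 for Cdc73, vehicle replicate 1, 2, 4 or 5 for Gm49599, fluoxetine replicate 4 or vehicle replicate 1, 3, 4 or 5 for Rpgrip1l and vehicle replicate 1, 2, 3 or 4 for Rpl21 (adjusted p from 0.0645 to 0.412).

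In the other fluoxetine comparisons limma called 0 genes. In HT-labelled males 752 genes had an unadjusted p under 0.05, and the smallest p values belonged to Tbx4 (−1.24 ± 0.241, adjusted p = 0.0655), Rpl14 (0.25 ± 0.055, 0.276) and Dnajb9 (0.20 ± 0.050, 0.785). In HT-labelled females 544 genes had one, led, apart from the Y-linked Eif2s3y, by Lcp2 and Ehd1. Eif2s3y lay between 0 and 4.19 normalized counts in these females and entered the test through the males, so no change is given for it. In WT-labelled females 1310 genes had one, led by Gm43039, Chmp2a and Vangl2 (adjusted p from 0.114 to 0.226). Limma without trend or robust shrinkage called 1, 0 and 1 genes in these comparisons, and the 1 in HT-labelled males was Tbx4 (adjusted p = 0.0248). With no filter on low values limma called 0, 9 and 0 genes. Cholesterol synthesis genes lay below 0 in all 4 fluoxetine comparisons, with medians of −0.128 in HT-labelled males (23 of 24 members), −0.050 in HT-labelled females (18 of 24), −0.112 in WT-labelled males (18 of 24) and −0.147 in WT-labelled females (23 of 24). The camera adjusted p was 7.03e-09, 0.0483, 0.00186 and 1.09e-07, and with an estimated correlation the adjusted p was 0.948, 0.749, 0.992 and 0.646. No member was called over all genes or adjusted over the list alone in any of the 4 comparisons. Myelin genes had medians of 0.21 and 0.438 in HT-labelled males and females and −0.213 in WT-labelled females (adjusted p = 0.948, 0.749 and 0.815 with an estimated correlation). In HT-labelled females, where 2 of the 4 fluoxetine libraries carried high striatal markers, striatal genes had a median of 0.299 (camera adjusted p = 0.0483, and 0.749 as the p with an estimated correlation). Tbx4 passed without HT-labelled fluoxetine male replicate 1 (adjusted p = 0.00338) or 5 (0.00586). Without HT-labelled vehicle female replicate 3 the count in HT-labelled females was 1, which was Eif2s3y with its few reads, and 1 gene was called in WT-labelled females without vehicle female replicate 2.

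Lithium was compared with vehicle in the same way. Genes of the endoplasmic reticulum and amino acid stress response, which encode chaperones and the transcription factor Atf4 with its targets, lay above 0 in 17 of 18 members in each of the 4 comparisons. Their medians were 0.186 in HT-labelled males, 0.096 in HT-labelled females, 0.153 in WT-labelled males and 0.126 in WT-labelled females. No member passed over all genes in any of them, and 11, 2, 4 and 0 passed adjusted over the list alone. The camera adjusted p was 4.59e-14, 1.68e-06, 1.58e-08 and 3.95e-08, and with an estimated correlation the adjusted p was 0.0687, 0.448, 0.436 and 0.587. Interferon response genes had medians of −0.107, −0.337, −0.192 and −0.11 in the same order, with 16 of 19 members below 0 in each and 0, 5, 0 and 1 lower adjusted over the list alone (camera adjusted p = 0.0414, 3.9e-09, 0.0156 and 0.00976, and 0.994, 0.26, 0.882 and 0.818 as the p with an estimated correlation). Oasl2, an interferon-induced gene, had −1.06 ± 0.219 in HT-labelled females (adjusted p = 0.0671). Immediate early genes had medians of 0.414 in HT-labelled females and 0.494 in WT-labelled males (0.729 and 0.436 as the p with an estimated correlation).

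Limma called 0 genes in each lithium comparison. The counts at an unadjusted p under 0.05 were 978 in HT-labelled males, 1009 in HT-labelled females, 1569 in WT-labelled males and 1104 in WT-labelled females, and limma without trend or robust shrinkage called 0, 0, 2 and 0. The smallest p values were those of Narfl, Cntln and Umps in HT-labelled males (adjusted p = 0.346), Fstl4 (0.42 ± 0.081, adjusted p = 0.0557), Ctnnb1 and Oasl2 in HT-labelled females, Pdrg1, Umps and Ahctf1 in WT-labelled males (0.0574) and Cwc27, Tubb3 and Slc1a1 in WT-labelled females (0.199 to 0.321). Striatal markers lay above 0 after lithium in males in 13 of 13 members, with medians of 0.352 in HT-labelled libraries (2 of 5 with high striatal markers) and 0.663 in WT-labelled libraries (1 of 5), and 0.994 and 0.882 as the adjusted p with an estimated correlation. Without the libraries of high striatal markers the list had a camera adjusted p of 0.885 and 0.14 in these comparisons. The count in WT-labelled males was 5 without lithium male replicate 2, 9 without lithium male replicate 5, 11 without vehicle male replicate 1, 4 without the libraries of high striatal markers and 60 with the first principal component as covariate, which also gave 4 in WT-labelled females. In HT-labelled females it was 1 without lithium female replicate 5, 2 without vehicle female replicate 1 and 7 without the libraries of high striatal markers.

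The genotype comparisons within each drug returned several of the genes seen in vehicle. With fluoxetine, HT-labelled males had lower Minar2 (−0.33 ± 0.054), Usp11 (−0.30 ± 0.050) and Tbrg1 (−0.25 ± 0.047) and higher Piga (0.42 ± 0.079), Oard1 (0.38 ± 0.073), Mettl4 (0.36 ± 0.074) and Tmem106c (0.34) beside Chd8. These made 8 genes called by limma, with 1763 at an unadjusted p under 0.05. In fluoxetine females 4 genes were called (1211 unadjusted), namely Chd8, Minar2 (−0.30 ± 0.057), 2900009J06Rik (1.12 ± 0.217) and Gm3693 (−0.54 ± 0.111), a gene model with near-identical copies and an uncertain value. With lithium, 9 genes were called in males (1590 unadjusted), among them Minar2 (−0.38 ± 0.054), Usp11 (−0.31 ± 0.050), Chmp2a (0.21 ± 0.035), Hexim1 (−0.25 ± 0.054), Crlf2 (0.45) and Fxyd2 (−0.71 ± 0.152), and 4 in females (849 unadjusted), namely Chd8, Dhx34 (0.52 ± 0.078), Minar2 (−0.36 ± 0.054) and Usp11 (−0.32 ± 0.050). Across the 6 genotype comparisons Chd8 was called in 6, Minar2 and Usp11 in 5 each and Chmp2a in 3, and each had the same sign in all 6. Myelin genes lay above 0 in 15 of 15 members with fluoxetine, with medians of 0.527 in males (0 called over all genes, 14 higher adjusted over the list alone) and 0.458 in females (0 and 0), and 0.709 and 0.858 as the adjusted p with an estimated correlation. Presynaptic vesicle release genes had medians of −0.078 in fluoxetine males and −0.107 in lithium males (0.974 and 0.713 as the p with an estimated correlation), and microglial genes one of −0.229 in fluoxetine females (0.146 as that p).

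Single libraries decided several of these calls. In fluoxetine males the count was 4 without WT-labelled replicate 4, 5 without WT-labelled replicate 3 or HT-labelled replicate 4, 16 without WT-labelled replicate 2, 19 without HT-labelled replicate 5 and 65 without WT-labelled replicate 5. There the calls of Piga (without WT-labelled replicate 3 or 4), Oard1 (HT-labelled replicate 2 or 4, WT-labelled 3 or 4), Mettl4 (HT-labelled 3 or 4, WT-labelled 1, 2, 3 or 4) and Tbrg1 (HT-labelled 4) ended with adjusted p from 0.0505 to 0.157. In fluoxetine females the count was 1 without HT-labelled replicate 1 or 3 or WT-labelled replicate 1 or 2 and 2 without HT-labelled replicate 2 or WT-labelled replicate 3, 4 or 5. There the calls of Minar2 (without HT-labelled replicate 1, 2 or 3 or WT-labelled replicate 1, 2, 4 or 5), 2900009J06Rik (HT-labelled 1 or 3, WT-labelled 1, 2 or 3) and Gm3693 (HT-labelled 1, 2 or 3, WT-labelled 1 to 5) ended with adjusted p from 0.0522 to 0.274. In lithium males the count was 4 without WT-labelled replicate 1, 5 without HT-labelled replicate 2 or 4 and 14 without HT-labelled replicate 1. Hexim1 lost its call without HT-labelled replicate 2, 3 or 4 or WT-labelled replicate 1 or 3 (adjusted p from 0.131 to 0.206), and Fxyd2 lost it without HT-labelled replicate 2, 3, 4 or 5 or WT-labelled replicate 1, 2 or 3 (0.0552 to 0.292). Fitted on their 2 groups alone, the 4 comparisons called 1, 0, 1 and 1 genes. Without the libraries of high striatal markers fluoxetine females and lithium males called 1 and 3, where Chmp2a (0.21), Usp11 (−0.29) and Hexim1 (−0.29) in lithium males had an adjusted p of 0.0504 with fewer libraries. With the striatal marker level as covariate these comparisons called 1 and 9. With no filter Hexim1 and Fxyd2 had 0.0891 and 0.0877, and with the first principal component as covariate 0.0718 and 0.074. The first principal component as covariate gave 123 genes in fluoxetine males and 7 in females with either drug, and no filter gave 11 and 7 in those females.

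Whether an effect differed between genotypes or sexes was tested by 7 interactions. Limma called 0 genes in each of them, also without trend or robust shrinkage. The counts at an unadjusted p under 0.05 were 576 for genotype by sex in vehicle, 844 and 782 for fluoxetine by genotype in males and females, 689 and 346 for lithium by genotype in males and females, and 399 and 390 for fluoxetine and lithium by sex in HT-labelled libraries. The smallest adjusted p was that of Cep97 for fluoxetine by genotype in males (0.68 ± 0.134, adjusted p = 0.0897). Over the 287 list tests of these interactions camera called 45 with a preset correlation and 0 with an estimated one. They included the immediate early genes for genotype by sex in vehicle, with a median of −0.552 and 18 of 18 members below 0 (adjusted p = 5.4e-06, and 0.933 as the p with an estimated correlation). Differences between strata in which genes passed are therefore not shown to be differences between the genotypes or sexes. For fluoxetine by genotype the count was 1 in males without HT-labelled vehicle male replicate 4 or WT-labelled fluoxetine male replicate 5 or with the first principal component as covariate, and 1 in females without WT-labelled vehicle female replicate 5, with no filter on low values or with the groups alone.

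The correlation of effects across genes addresses whether a drug moved genes against the genotype. Across 16839 genes, which are not independent replicates, the HT-labelled minus WT-labelled difference in vehicle correlated with the fluoxetine difference in HT-labelled libraries at r = −0.503 in males and −0.436 in females, and with the lithium difference at −0.453 and −0.441. Both differences use the same HT-labelled vehicle libraries, and groups simulated without any effect gave mean r of −0.493, −0.471, −0.463 and −0.501 over 100 simulations each. The covariance exceeded the simulated one by 0.00107, 0.00464, 0.00114 and 0.00318, against simulated SDs of 0.014, 0.012, 0.011 and 0.010. With the HT-labelled vehicle libraries split between the 2 differences, the mean r over 20 splits was 0.0393, 0.0813, 0.0739 and 0.0572. A movement of genes by either drug against the genotype was thus not separable from the shared libraries. The fluoxetine and lithium differences, which share their vehicle libraries, correlated at 0.427 to 0.52, with simulated means of 0.456 to 0.49 and split means of −0.0452 to 0.0118. For pairs of differences with no shared library, 11 values of r between −0.0142 and 0.24 lay inside their simulated ranges.

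Sex was compared in the WT-labelled vehicle libraries. Xist rose in females by 12.7 ± 0.793, and the X-linked genes Eif2s3x (0.54 ± 0.039), Kdm5c (0.33 ± 0.046) and Ddx3x (0.26 ± 0.050), which escape X inactivation, were higher as well, with 5530601H04Rik (0.42 ± 0.083). The Y-linked genes Uty, Kdm5d, Ddx3y, Eif2s3y and Uba1y and the gene model Gm29650 were lower in females, with log2 differences from −10.53 (Eif2s3y) to −4.66 (Uba1y). These 11 genes (5 higher, 6 lower) were all that limma called, with 531 at an unadjusted p under 0.05. Log2 fold changes of genes near 0 in one sex depend on the added 1.

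Because single comparisons called few genes, the same model was also read as averages over strata, a choice made after those counts were seen. Averaged over sexes and treatments, the 29 HT-labelled libraries differed from the 30 WT-labelled libraries in 1344 genes by limma (618 higher, 726 lower). Minar2 fell by 0.32 ± 0.022 and Usp11 by 0.29 ± 0.021, followed by Smyd5 (−0.28 ± 0.036), Orai2 (−0.23 ± 0.029), which encodes a calcium channel of store-operated entry, Hexim1 (−0.17 ± 0.022), an inhibitor of the elongation kinase P-TEFb, and the synaptic vesicle gene Syngr3 (−0.17 ± 0.022). Among genes that rose were Chmp2a (0.18 ± 0.014), Oard1 (0.29 ± 0.030), Tmem106c (0.26 ± 0.029) and Dhx34 (0.27 ± 0.032), an RNA helicase of nonsense-mediated decay. Minar2, Usp11, Orai2, Hexim1, Syngr3, Chmp2a, Oard1, Tmem106c and Dhx34 had the same sign in 6 of 6 strata, and their adjusted p ranged from 7.64e-16 to 6.82e-07. Rps4l also rose (0.40 ± 0.056), but it has near-identical copies and its value is uncertain. With no filter on low values 877 genes were called.

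Most genes of the synaptic lists lay below 0 in the HT-labelled libraries. Of 25 glutamatergic postsynaptic genes 23 lay below 0 (median −0.061), with 4 called lower over all genes, Gria3 (−0.12 ± 0.034), Nlgn3 (−0.079 ± 0.022), Dlg3 (−0.056 ± 0.016) and Dlgap1 (−0.070 ± 0.023), and 12 adjusted over the list alone (camera adjusted p = 3.29e-05, and 0.75 as the p with an estimated correlation). A permutation test of the list mean, adjusted over the 41 lists, gave 0.0348 for this list, 0.0583 for the presynaptic and 0.0383 for the GABA receptor list. With the first principal component as covariate these p were 0.00697, 0.0691 and 0.0691, and the list means went from −0.0574 to −0.0376, −0.0688 to −0.031 and −0.054 to −0.035. Of 19 presynaptic vesicle release genes 19 lay below 0 (median −0.078), with 3 called, among them Syn2 (−0.11 ± 0.027) and Vamp2 (−0.078 ± 0.022), and 5 adjusted over the list alone. Of 15 GABA receptor genes 13 lay below 0 (median −0.049), with 1 called and 2 adjusted over the list alone. Glycolysis genes had a median of −0.047 (2 of 17 called lower, 6 adjusted over the list alone), glucocorticoid response genes −0.088 (2 of 14 called lower, Nfkbia and Zbtb16, 5 adjusted over the list alone), myelin genes 0.174 (1 of 15 called higher, 1 adjusted over the list alone) and interferon response genes 0.074 (Ifit1 and Usp18 higher and Ifi27 lower, the same counts adjusted over the list alone). Each of these lists had a camera adjusted p between 0.000118 and 0.0269 and 0.75 as the p with an estimated correlation. Autism risk genes had a median of −0.026 (camera adjusted p = 0.0664), with 2 of 32 called and 5 lower adjusted over the list alone. The excitatory neuron markers, which follow the first principal component, had a median of −0.113 in the same comparison (0.75 as the p with an estimated correlation), and the olfactory bulb markers had one of 0.298 (0.875 as that p), while with that component as covariate their mean went from 0.325 ± 0.55 to −0.443 ± 0.18. Upper layer neuron markers had a list mean of −0.065 ± 0.021 and astrocyte markers one of 0.056 ± 0.019 (adjusted permutation p = 0.0383 each), and with the component as covariate these p were 0.0884 and 0.0886. The same test gave 0.0383 for the 2 ependymal markers (0.135 ± 0.049) and for heat shock chaperones (0.0501 ± 0.017), and 0.0886 and 0.0691 with that covariate. With that component as covariate the camera p of the glycolysis and interferon lists rose above 0.05 (0.0769 both). That of the other 5 lists stayed under 0.05.

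Averaged over sexes and genotypes, lithium changed 742 genes by limma (471 higher, 271 lower; 20 lithium and 20 vehicle libraries). The endoplasmic reticulum and amino acid stress list rose as a group. Its 18 members all lay above 0 (median 0.131), 12 were called higher over all genes and 15 adjusted over the list alone, and camera passed with the preset and with the estimated correlation (adjusted p = 1.38e-16, and 0.0295 as the p with an estimated correlation). Atf4, the transcription factor of the amino acid response, rose by 0.17 ± 0.027, the chaperone genes Hspa5, Sdf2l1 and Hyou1 by 0.22 ± 0.052, 0.37 ± 0.070 and 0.16 ± 0.030, and the leucine sensor gene Sesn2 by 0.22 ± 0.047. Impa1, which encodes the inositol monophosphatase that lithium inhibits, rose by 0.15 ± 0.025, and Slc5a3, a myo-inositol transporter gene, by 0.19 ± 0.036. These and Bpnt1 (0.077 ± 0.023) were the 3 of 11 inositol cycle genes called, and also the 3 adjusted over the list alone. That list passed no camera test (adjusted p = 0.379 and 0.886), and its median (0.0011) and mean (−0.023) differ in sign. Ctnnb1, the gene of beta-catenin, fell by 0.18 ± 0.023, and its Wnt target list had 1 of 13 members called, Ccnd1 (0.17 ± 0.044), also 1 adjusted over the list alone (camera adjusted p = 0.216). The other way from Ccnd1, 10 of the 13 lay below 0 (median −0.061), and the list mean was −0.093 ± 0.038 (permutation p = 0.0132, or 0.0902 adjusted over the 41 lists). Castor2, a gene of the mTORC1 pathway, rose by 0.20 ± 0.025 and Umps, an enzyme of pyrimidine synthesis, by 0.19 ± 0.025. The glutamate transporter gene Slc1a1 rose by 0.11 ± 0.018, while the kinase gene Pnck fell by 0.28 ± 0.045. Atf4, Hspa5, Impa1, Ctnnb1, Castor2, Umps, Slc1a1 and Pnck had the same sign in 4 of 4 strata. None of their calls ended when any 1 of the 40 libraries was left out. Other lithium calls were less stable. Chac1 (0.20) and Col3a1 (−0.39) had their sign in 3 of 4 strata. Leaving out 1 library ended the call of Chac1 in 18 of 40 fits and that of Lum (−0.45) in 23 of 40. With no filter on low values, Chac1 and Lum had a limma adjusted p of 0.078 and 0.0859. The count was 483 with no filter on low values and 1472 with the first principal component as covariate.

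Oxidative phosphorylation genes had a median of 0.044 after lithium, with 17 of 76 called higher over all genes, among them Cox6b1 (0.16) and Atp5k (0.13), and 28 adjusted over the list alone (camera adjusted p = 3.96e-10, and 0.597 as the p with an estimated correlation). Interferon response genes lay below 0 in 18 of 19 members (median −0.179), with Rsad2 (−0.52 ± 0.104) and Oasl2 (−0.44 ± 0.11) called lower and 7 adjusted over the list alone (adjusted p = 5.19e-07, and 0.414 as the p with an estimated correlation). A permutation test of the list mean, adjusted over the 41 lists, gave 0.00943 for the interferon list and 0.0154 for the meningeal list given next. Meningeal fibroblast markers, which include collagen genes and are not cortical parenchyma, lay below 0 in 11 of 11 (median −0.299), with 3 called, among them Col3a1 (−0.39 ± 0.106, and an adjusted p of 0.0708 without the libraries of high striatal markers), and 10 adjusted over the list alone (adjusted p = 2.03e-07, and 0.582 as the p with an estimated correlation). Immediate early genes had a median of 0.22, with Nptx2 (0.19 ± 0.047) and Jun (0.16 ± 0.048) called and 5 adjusted over the list alone (0.828 as the p with an estimated correlation). Striatal markers had a median of 0.194 with 1 of 13 called, Pde10a (0.47 ± 0.124), also 1 adjusted over the list alone (camera adjusted p = 0.0419, and 0.927 as the p with an estimated correlation), and blood markers one of −0.37 with 0 of 5 called and 3 adjusted over the list alone (0.828 as that p).

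**Figure D3:**
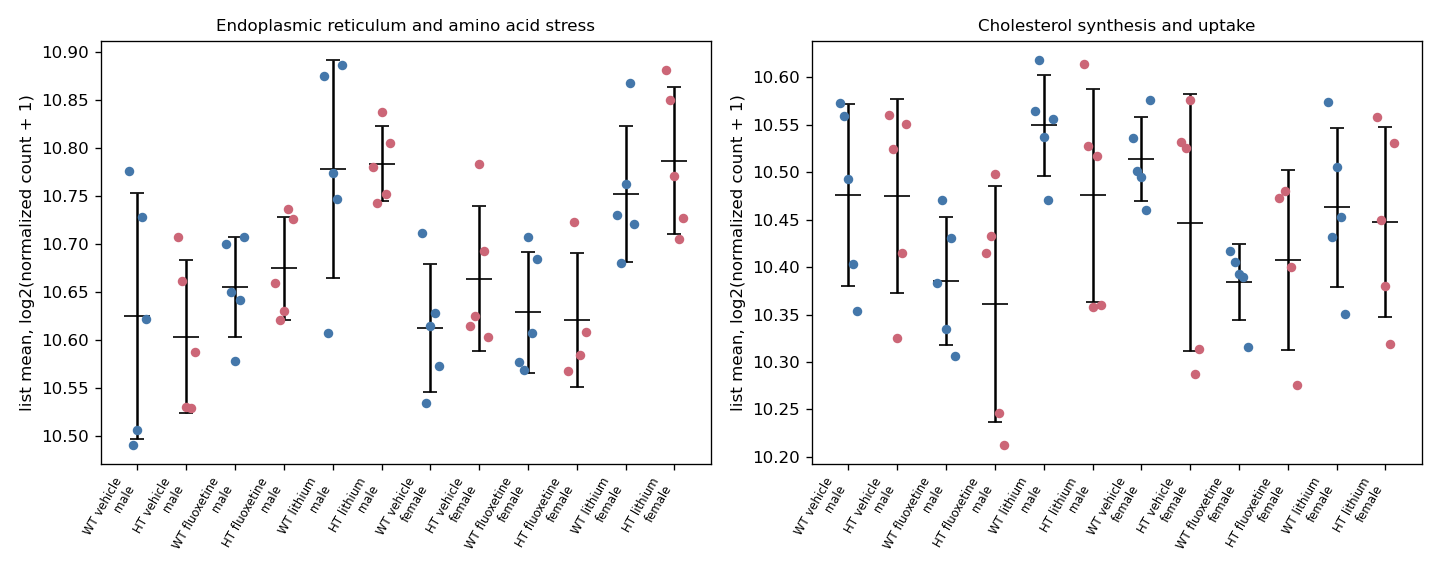
Mean log2(normalized count + 1) over the genes of the endoplasmic reticulum and amino acid stress list (left) and of the cholesterol synthesis and uptake list (right) in each library (points, blue for WT-labelled and red for HT-labelled), with the mean and SD of each group (bars). Averaged over the 4 strata, the stress list lay 0.149 higher with lithium and the cholesterol list 0.0936 lower with fluoxetine.

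Averaged over sexes and genotypes, fluoxetine changed 11 genes by limma (6 higher, 5 lower; 19 fluoxetine and 20 vehicle libraries). Rpl14 rose by 0.16 ± 0.028, Rpl21 by 0.11 ± 0.022 and Rps15 by 0.13 ± 0.028, with Dcaf4 (0.19 ± 0.038), Edf1 (0.12 ± 0.026) and Chmp2a (0.081 ± 0.018). Rpl14 had this sign in 3 of 4 strata, with −0.01 ± 0.059 in HT-labelled females, and Rpl21, Rps15, Cdc73 and Stard4 had theirs in 4 of 4. The values of the 3 ribosomal protein genes are uncertain, since near-identical copies exist. Cdc73 fell by 0.21 ± 0.039, Stard4, a cholesterol carrier gene, by 0.19 ± 0.039, Phf3 by 0.13 ± 0.028 and Ncoa6 by 0.12 ± 0.022, and the gene model Gm43039 was lower as well. Cholesterol synthesis genes lay below 0 in 22 of 24 members (median −0.095), of which 1, Stard4, was called over all genes and 14 adjusted over the list alone (camera adjusted p = 1.83e-12, and 0.536 as the p with an estimated correlation). Sqle (−0.15 ± 0.037) and Insig1 (−0.12 ± 0.031) had adjusted p of 0.0764 and 0.0724. Cytosolic ribosomal proteins had a median of 0.045 (3 of 78 called, 15 adjusted over the list alone, 0.545 as the p with an estimated correlation), and meningeal fibroblast markers one of −0.254 (0 of 11 called, 0 adjusted over the list alone, 0.545 as that p). Serotonin signalling genes had a median of 0.0086 with 0 of 14 called, also 0 adjusted over the list alone (camera adjusted p = 0.96).

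The count after fluoxetine depended on single libraries. It was 43 with the first principal component as covariate, where Sqle and Insig1 passed (adjusted p = 0.000328 and 0.00207). Of the HT-labelled libraries, it was 28 without fluoxetine female replicate 4, 32 without fluoxetine male replicate 4, 22 without vehicle female replicate 1 and 74 without vehicle male replicate 1. Of the WT-labelled libraries, it was 53 without fluoxetine male replicate 5, 24 without vehicle male replicate 1 and 18 without vehicle female replicate 1 or 3. It was 4 without WT-labelled fluoxetine male replicate 1 and between 5 and 7 without HT-labelled fluoxetine female replicates 1, 2 or 3, fluoxetine male replicates 1 or 2, vehicle female replicates 3 or 5 or vehicle male replicates 2 or 3, or without WT-labelled fluoxetine female replicates 3 or 4, fluoxetine male replicate 2, vehicle female replicates 4 or 5 or vehicle male replicates 2 or 3. The call of Stard4 ended without any of 10 of the 39 libraries, HT-labelled fluoxetine female replicates 1 and 3, fluoxetine male replicates 1 and 5, vehicle female replicate 3 and vehicle male replicate 2, and WT-labelled fluoxetine male replicate 1, vehicle female replicate 5 and vehicle male replicates 2 and 3 (adjusted p from 0.0502 to 0.0614), and that of Rps15 without any of 22 (0.0525 to 0.121). These were HT-labelled fluoxetine female replicates 1 to 3, fluoxetine male replicates 1 and 2, vehicle female replicates 2, 3 and 5 and vehicle male replicates 2 to 4. The others were WT-labelled fluoxetine female replicates 2 and 3, fluoxetine male replicates 1, 2 and 4, vehicle female replicates 4 and 5 and vehicle male replicates 2 to 5. The count was 13 with the striatal marker level as covariate, with the 11 genes above among them, and 1 without the 8 libraries of high striatal markers, a fit with fewer libraries. There Rpl14 (0.13), Rpl21 (0.10), Cdc73 (−0.20) and Stard4 (−0.19) had an adjusted p of 0.228 and Rps15 (0.10) one of 0.396. With no filter on low values the count was 4, and Rps15 and Stard4 had 0.0978 and 0.0648. Limma without trend or robust shrinkage called 7 and gave Rps15 0.059.

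Averaged over genotypes and treatments, sex changed 26 genes by limma (14 higher and 12 lower in the 29 female libraries). Beside the sex-linked genes above, the X-linked Kdm6a (0.47 ± 0.046), Jpx (0.38 ± 0.056) and Pbdc1 (0.16 ± 0.027) were higher in females. Lower in females were Il33 (−0.30 ± 0.050), an alarmin gene of glia, Serpina3n (−0.20 ± 0.042), an acute-phase protease inhibitor gene, and the protocadherin gene Pcdhga1 (−0.27 ± 0.049), with adjusted p from 0.00028 to 0.0135. Immediate early genes had a median of −0.155 with 18 of 18 members below 0 and 0 called over all genes or adjusted over the list alone (camera adjusted p = 6.31e-05, and 0.819 as the p with an estimated correlation). The count of genes was 73 with the first principal component as covariate.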

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

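The tests of the scaling, of single and exchanged labels, of the first principal component, of myelin and astrocyte genes, and of libraries with high striatal markers were chosen after the results were seen. The tests of the genes around Chd8, of the spread between libraries and of other splits were chosen before their own values were seen, but those on averaged comparisons concern comparisons added after the counts of single strata were seen.

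Chd8 was higher in the HT-labelled libraries, although a heterozygous mutation that lowers the RNA of its gene would make it lower there. Single wrong labels are argued against, as 0 libraries lay within the range of the other label, and so is the scaling, as TMM factors gave a difference of 0.7. A change shared by the surrounding genes is argued against by 12 tested genes within 1 Mb, of which 0 were called by limma, with a median of 0.051 and a largest value of 0.455 for Rpgrip1 (adjusted p = 0.0514). HT and WT labels exchanged throughout the series would give the observed 0.695 without overlap, as would an allele whose RNA is more abundant, and these cannot be told apart, because the deposited table holds no other measure of the genotype. Every genotype direction may therefore be the reverse of the one given.

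The mean log2 change of the cholesterol synthesis list after fluoxetine was −0.0936 ± 0.03 (SE), averaged over sexes and genotypes, with −0.114 and −0.0396 in HT-labelled males and females and −0.0912 and −0.13 in WT-labelled males and females. The mixture of tissues along the first principal component is argued against as the whole cause, since the mean was −0.123 ± 0.018 with that component as covariate, and so is the scaling (−0.0933 with TMM factors). The permutation p of the list mean was 0.00419, or 0.172 adjusted over the 41 lists among which it was picked. With the component as covariate it was 1e-05, the smallest that the permutations can give, or 0.00041 adjusted over the lists, which argues against the spread between libraries, although that covariate was chosen after the data were seen. Fewer astrocytes are argued against by their list mean of 0.0063 ± 0.023, but fewer oligodendrocytes and a change by the drug cannot be told apart, because the myelin list mean of 0.0747 ± 0.11 is too uncertain.

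The mean of the endoplasmic reticulum and amino acid stress list was 0.149 ± 0.025 (SE) higher after lithium, with 0.18 and 0.123 in HT-labelled males and females and 0.154 and 0.14 in WT-labelled males and females. The mixture along the first principal component (0.151 with it as covariate), the scaling (0.147 with TMM factors) and striatal RNA in some libraries (0.172 without the 8 libraries of high striatal markers) are argued against as the whole cause. The spread between libraries is argued against by a permutation p of 3e-05, or 0.00123 adjusted over 41 lists. A response of these genes to lithium is a hypothesis found and tested on the same data. Food intake, maternal care and litter were not recorded in the labels and stay open.

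Of 84 tests of 7 measures in 12 groups, 11 (13.1%) found a library far from the others of its group, where chance gives about 1 in 20. Chd8 was lowest in HT-labelled vehicle female replicate 4, at 5115 normalized counts against 5840 in the nearest library. The mean log2 level of the striatal markers was highest in HT-labelled vehicle female replicate 3 (10.16, nearest 8.186), HT-labelled vehicle male replicate 4 (8.843, nearest 8.236), WT-labelled fluoxetine female replicate 1 (9.042, nearest 8.12), WT-labelled lithium female replicate 1 (9.007, nearest 8.357), WT-labelled lithium male replicate 2 (11.03, nearest 8.371) and WT-labelled vehicle female replicate 5 (9.718, nearest 8.384). The meningeal level was highest in WT-labelled vehicle male replicate 5 (9.954, nearest 9.07), the choroid plexus level in WT-labelled fluoxetine male replicate 5 (7.556, nearest 4.872) and the blood level in HT-labelled vehicle female replicate 1 (11.15, nearest 10.38). The olfactory bulb level was lowest in WT-labelled vehicle female replicate 3 (5.008, nearest 8.514).

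Each count of genes was set against 100 splits of the same libraries into groups of the same sizes, the real split included. Fewer than 5 splits called as many genes for genotype in vehicle males (4 genes, 2 splits with as many, highest other 123) and females (5, 1 split, highest other 2), for genotype in fluoxetine females (4, 1 split, highest other 2), lithium males (9, 2 splits, highest other 12) and lithium females (4, 1 split, highest other 1), and for sex in WT-labelled vehicle libraries (11, 1 split, highest other 7). The same held for the averaged comparisons of genotype (1344, 1 split, highest other 1113), fluoxetine (11, 2 splits, highest other 3089), lithium (742, 3 splits, highest other 1554) and sex (26, 1 split, highest other 2). With 100 splits and no adjustment over the comparisons, such counts argue against chance but do not exclude it. Chance was not argued against for fluoxetine in WT-labelled males (5, 5 splits, highest other 108) or genotype in fluoxetine males (8, 5 splits, highest other 405). For the comparisons that called 0 genes, 100 of 100 splits gave as many. Their highest other counts were 4278, 1 and 1 for fluoxetine in HT-labelled males, HT-labelled females and WT-labelled females, and 4448, 29, 4 and 2 for lithium in HT-labelled males and females and WT-labelled males and females. For the interactions they were 2862 for genotype by sex, 1032 and 0 for fluoxetine by genotype in males and females, 3 and 3 for lithium by genotype, and 1039 and 2120 for fluoxetine and lithium by sex. Splits that called many times the real number of genes, as for both drugs in HT-labelled males, point to a structure of the samples that the groups do not describe. The splits took no account of replicate numbers, between which scores on the first principal component differed (permutation p = 0.00013).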

How the results depend on the processing

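The covariates and the meningeal list without each library were added after the data were seen. So were the fits without 8 libraries of high striatal markers and the averaged contrasts with all their alternatives. No correlation and no called gene that was followed through the alternatives reversed its direction. No list followed in this way passed in opposite directions. Counts have no direction, and some named genes, such as Smyd5 and Sdf2l1, were not followed. Of 123 list means of the averaged genotype, fluoxetine and lithium contrasts, 28 changed sign with the first principal component as covariate. Of these 28, 0 lay over 2 SE from 0 without it and 1 with it, that of olfactory bulb markers by genotype (0.325 ± 0.55 to −0.443 ± 0.18). The mean of the same markers went from −0.615 to 0.16 after fluoxetine and from −0.335 to 0.209 after lithium. A pseudocount of 0.5 moved none of 31 counts and correlations and changed the side of the threshold for none of 66 single genes and lists. TMM factors moved 2 of 32 counts and correlations by over 1.5 times. With the groups of a contrast alone, 30 calls of a followed gene in a comparison no longer passed. They included all 5 genotype calls of Minar2, all 5 of Usp11 and all 3 of Chmp2a. Outside these 30, Chd8 lost its genotype call in fluoxetine females, where 0 genes were called with the groups alone. The cause was not tested except where fewer libraries or more genes entered a test.

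With the groups of a contrast alone, which leaves fewer libraries to estimate the spread, genotype gave 1 gene in vehicle males, 2 in vehicle females, 1 in fluoxetine males, 0 in fluoxetine females, and 1 in lithium males and 1 in lithium females. Fluoxetine gave 0 in WT-labelled males and 1 in WT-labelled females, lithium gave 1 in HT-labelled males, and fluoxetine by genotype in females gave 1. Limma without trend or robust shrinkage gave 1 for fluoxetine in HT-labelled males, 3 in WT-labelled males, 1 in WT-labelled females and 7 averaged, and 2 for lithium in WT-labelled males. TMM factors gave 3 for fluoxetine in WT-labelled males and 1 for lithium in HT-labelled females. With no filter, where more genes were tested, fluoxetine in HT-labelled females gave 9, lithium in HT-labelled males 1 and in WT-labelled males 1, genotype in fluoxetine females 11 and in lithium females 7, fluoxetine by genotype in females 1, and the averages over strata 877 for genotype, 4 for fluoxetine and 483 for lithium.

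With the first principal component as covariate, genotype gave 15 in vehicle females, 123 in fluoxetine males, 7 in fluoxetine females and 7 in lithium females, fluoxetine gave 38 in WT-labelled males and 1 in WT-labelled females, and lithium gave 2 in HT-labelled females, 60 in WT-labelled males and 4 in WT-labelled females. Fluoxetine by genotype in males gave 1, and the averages gave 43 for fluoxetine, 1472 for lithium and 73 for sex. With the striatal level as covariate, genotype in fluoxetine females gave 1. Without the libraries of high striatal markers, genotype gave 8 in vehicle females, 1 in fluoxetine females and 3 in lithium males. Lithium then gave 7 in HT-labelled females and 4 in WT-labelled males, and averaged fluoxetine gave 1. The correlation of genotype and drug effects was then −0.338 for fluoxetine in females and −0.365 for lithium in males. Of 574 list tests, 106 passed with the preset correlation, 0 with an estimated correlation and 1 with fry.

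The samples share only a number, and no label says that equal numbers mark a litter or a batch. As a replicate block, the number gave 9 genes for genotype in vehicle females, 10 in fluoxetine females and 17 in lithium males, 1 for fluoxetine in HT-labelled males, 8 in WT-labelled males and 41 averaged, and 5 for lithium in HT-labelled females and 47 in WT-labelled males. Sqle and Insig1 after averaged fluoxetine passed with it (adjusted p = 0.0467 and 0.0277). Over 68 pairs of equal number, correlations of residual values ran from −0.37 to 0.553, with 29 over 0.1 and a mean of 0.0789 against −0.0196 for unequal numbers, and 19 of 59 libraries correlated best with their own number. Scores on the first principal component averaged −15.6, −11.5, 0.529, 13.4 and 14.5 for numbers 1 to 5 (permutation p = 0.00013). Every gene called without the block was also called with it. With equal groups the fold change stays the same under a block, so a gained call is not a larger effect.

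Leaving out 1 library at a time, counts ranged from 2 to 7 for genotype in vehicle females, 4 to 65 in fluoxetine males, 1 to 5 in fluoxetine females and 4 to 14 in lithium males. They ranged from 0 to 1 for fluoxetine in HT-labelled males, 0 to 1 in HT-labelled females, 1 to 106 in WT-labelled males, 0 to 1 in WT-labelled females and 4 to 74 averaged, from 0 to 2 for lithium in HT-labelled females and 0 to 11 in WT-labelled males, and from 0 to 1 for fluoxetine by genotype in males and 0 to 1 in females. The correlation of genotype and fluoxetine effects ranged from −0.618 to −0.442 in males and −0.54 to −0.36 in females, and that of genotype and lithium effects from −0.557 to −0.351 in males and −0.556 to −0.385 in females. Other counts stayed within 1.5 times, among them 1097 to 1677 for averaged genotype and 561 to 881 for averaged lithium.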

Other observations

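Microglial genes had a median log2 difference of 0.057 between female and male libraries, averaged over genotypes and treatments, with 12 of 13 members above 0, and endothelial genes one of 0.049 with 9 of 10 above 0. No member of either list was called over all genes or adjusted over the list alone (camera adjusted p = 0.000443 and 0.0224, and 0.819 as the p of both with an estimated correlation). After fluoxetine, averaged over sexes and genotypes, glycolysis genes had a median of 0.057 with 16 of 17 above 0 (1 adjusted over the list alone), proteasome subunits one of 0.033 with 32 of 38 above 0 (4 adjusted over the list alone) and mitochondrial ribosomal proteins one of 0.033 with 61 of 78 above 0 (5 adjusted over the list alone), with 0 called over all genes in each. Their camera adjusted p was 2.6e-05, 2.4e-06 and 2.45e-06, and with an estimated correlation the adjusted p was 0.545, 0.539 and 0.536. Glycolysis genes followed the first principal component, with a median correlation of −0.761. Averaged over strata, 79 genes were called both by genotype and by lithium, 2 by genotype and by fluoxetine, and 1 by lithium and by fluoxetine. These overlaps come from 1344 calls for genotype, 742 for lithium and 11 for fluoxetine among 16839 genes. They were not tested against chance, and their directions were not compared, so they do not show that a drug acts on the genotype genes.

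In WT-labelled females given lithium, blood markers had a median of −0.689 (camera adjusted p = 0.000513, and 0.818 as the p with an estimated correlation) and meningeal fibroblast markers one of −0.379 (0.000171, and 0.818 as the p with an estimated correlation). With 0 members called over all genes or adjusted over the list alone, both lists lay below 0 in every member, 5 of 5 and 11 of 11.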
